A study of Mus musculus with 12 samples.

How the data were processed

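The series holds 12 mouse RNA-seq libraries, 3 in each of 4 donor genotypes, prepared per the labels from poly(A)-selected RNA with unstranded TruSeq libraries. Per the file headers the deposited gene tables have the columns of RSEM, with expected counts, TPM and the length and effective length of each gene in bases. The submitters' processing notes name bcl2fastq and the mm10 genome. The versions of bcl2fastq and RSEM and the aligner are not given in the sources used here. Expected counts are the authors' estimates of fragments per gene and were not normalized. TPM values, deposited by the authors and summing to the same total in each library, were not used for tests. Genes are named by symbol, and chromosome positions come from a GRCm38 annotation.

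Groups were taken from the labels. The tests, gene lists, rule for named genes and processing alternatives were set before the data were examined, except for 3 alternatives described below and some tests of explanations, which are named where they are given. Expected counts were rounded to whole numbers and filtered with filterByExpr by group, which kept 13755 of 24411 genes. They were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) in 1 quasi-likelihood model with robust dispersion over the 4 groups. Of 8 contrasts, 5 compare a pair of groups, 1 tests the interaction and 2 average the effect of an allele over the other's status. P-values are two-sided and adjusted by Benjamini-Hochberg over the tested genes, with 0.05 as the limit. Standard errors of log2 fold changes come from the quasi-likelihood F statistic. Library totals ran from 73074797 to 86555638 expected counts, and summed counts of genes near 0 carry counting error only. Reads shared between near-identical gene copies, or antisense to a gene in unstranded libraries, cannot be assigned with certainty.

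A set of 30 gene lists covering cell types, stress, cell cycle, metabolism and splicing was fixed, and 29 with at least 5 tested members were tested. No mitochondrially encoded gene is in the tables, so that list has no value. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data, and with fry. For each list the number of genes that pass when p-values are adjusted over the list alone is given beside the number adjusted over all genes. The named genes of a contrast are Mecom, Sf3b1, Gata2 and Rpn1, the 8 genes with the largest rise and the 8 with the largest fall among genes that passed with a mean of at least 2 CPM and no overlap between groups (not asked of the interaction), and up to 4 members of each list with the smallest p. Predicted genes and pseudogenes were not named. Some results for single genes are not reported here. Isoform use was tested with limma (trend, robust) on log2 effective length in 3422 genes with at least 50 expected counts in every library and more than 1 listed transcript.

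The code was tested on simulated data for Sf3b1 K700E against control with 13755 genes, 200 of them changed. It recovered 100% of genes lowered by 2 log2 units, 87.5% and 92.5% of those changed by -1 and 1, and 77.5% and 70% of those changed by -0.5 and 0.5. It called 13 unchanged genes, and 0 genes in an unchanged comparison of inv(3) with control. Of 29 simulated lists the 1 that was moved was called and none of the others. These lists were random genes simulated independently of each other, so they do not show how often camera calls lists of correlated genes. For length, all 40 changed genes of 3422 were recovered with 3 calls among unchanged genes.

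Alternatives were RLE scaling, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, the libraries of the compared groups alone, the replicate number as a block, an effective-length offset, abundant genes left out before scaling, and each library left out in turn. For length they included the length column in place of effective length and a minimum of 200 counts. After the data were seen, 3 more were added: autosomal genes alone, the 9 libraries with Y-linked RNA, and log2 Xist as a covariate in those 9. Every contrast was repeated on other splits of the same libraries.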

Results

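RNA was sequenced from lineage-negative, cKit-positive bone marrow cells, a gate that holds hematopoietic stem cells and progenitors. The cells came from femora and tibiae of CD45.1 recipient mice that had been given CD45.2 donor marrow together with wild-type CD45.1 support marrow. Whether CD45.2 donor cells were sorted from recipient and support cells is not given in the sources used here. Donor cells carried the pIpC-inducible Mx1-Cre transgene alone (control), with the inv(3) allele, with the heterozygous splicing-factor mutation Sf3b1 K700E, or with both alleles (double group). Each of the 4 groups had 3 libraries, taken 6 months after 3 doses of pIpC at 20 mg/kg. The inv(3) rearrangement moves a GATA2 enhancer next to EVI1 (Mecom in mouse), and the series asks how splicing of EVI1 bears on leukemia with that rearrangement. Library totals were 76153040 to 79905476 expected counts in control, 76593862 to 84215333 in inv(3), 73074797 to 86555638 in Sf3b1 K700E and 76763188 to 84185031 in the double group. Of 24411 genes listed, 13755 were tested. The labels do not say whether the replicates are separate mice, so the p-values measure the spread between these samples.

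The first principal component, with 66.6% of the variance, parted libraries with the inv(3) allele from those without it. Control libraries lay between -45.2 and -43.6 and Sf3b1 K700E libraries between -63.9 and -55.4, whereas inv(3) libraries lay between 44.8 and 68.5 and double libraries between 47.1 and 49.7. The second component took 13.3% and parted the double libraries (21.9 to 36.5) from the inv(3) libraries (-46.8 to -12.1).

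**Figure D1:**
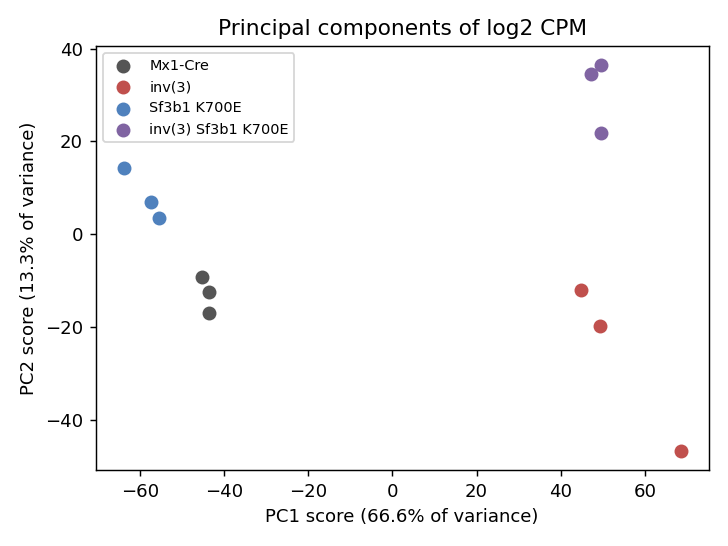
First and second principal component of log2 CPM (counts per library size scaled by TMM), 1 point per library, colored by group, with the share of the variance on each axis. The 6 libraries with inv(3) lie at 44.8 or above on the first axis and the 6 without it at -43.6 or below.

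Sex-linked transcripts set the inv(3) group apart from the other 3. Xist, the RNA that silences an X chromosome in female cells, was 1952 ± 151 CPM (SD, n = 3) in inv(3), against 32.9 ± 8.11 in control and 30.4 ± 9.0 in the double group. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 4 to 8 counts in each inv(3) library and 19200 to 25380 in each of the other 9. Sf3b1 K700E libraries had both Y-linked RNA and Xist at 159 ± 71.7 CPM (SD, n = 3), which is 3.95% to 10.7% of the inv(3) mean, against 1.23% to 2.04% in control. The labels give no sex for donors or recipients. Comparisons of inv(3) with control and of the double group with inv(3) therefore also compare libraries without and with Y-linked RNA, and the interaction and both averaged effects, which use the inv(3) group, carry the same difference, while the comparisons among control, Sf3b1 K700E and the double group do not.

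**Figure D2:**
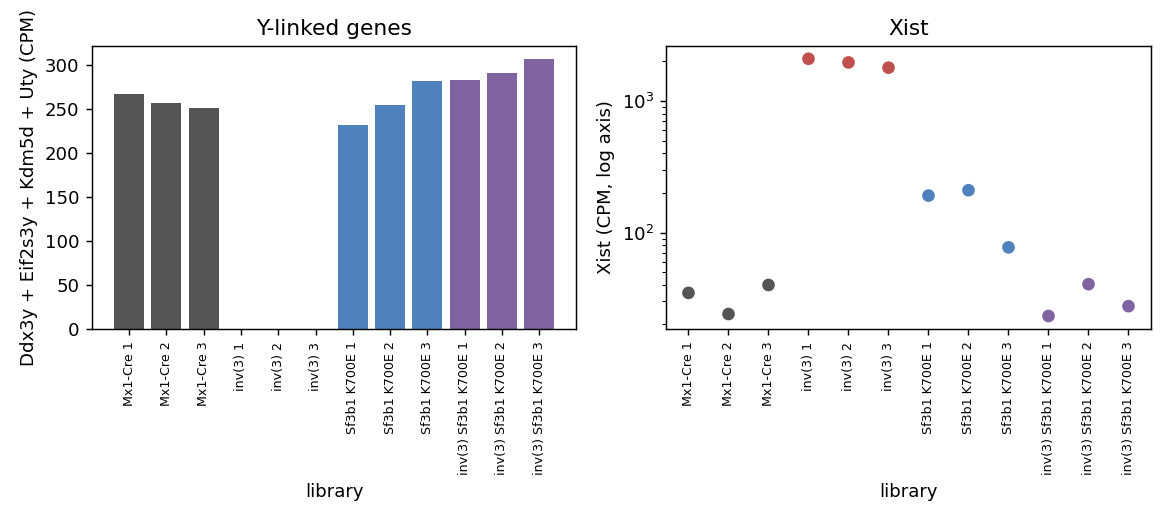
Left, summed CPM of 4 Y-linked genes in each library. Right, Xist CPM on a log axis. The 3 inv(3) libraries have 4 to 8 Y-linked counts, and their Xist lies between 1790 and 2100 CPM.

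The genes the alleles concern were read in every library first. Mecom (chromosome 3, 29951296 to 30509759, GRCm38), a zinc-finger transcription factor of hematopoietic stem cells, was 6.15 ± 0.583 CPM (SD, n = 3) in control, 4.58 ± 1.14 in inv(3), 8.48 ± 2.18 in Sf3b1 K700E and 10.2 ± 1.12 in the double group. It was higher in the double group than in inv(3) by 1.15 ± 0.20 log2 units (SE, n = 3 per group, adjusted p = 0.0031) and higher than in control by 0.72 ± 0.20 (adjusted p = 0.011). Between inv(3) and control its difference of -0.42 ± 0.20 did not pass (adjusted p = 0.11), nor did that of 0.46 ± 0.20 between Sf3b1 K700E and control (adjusted p = 0.16). With effective length as an offset, inv(3) differed from control by -0.67 (adjusted p = 0.016), and the double group from control by 0.47 (adjusted p = 0.062). Gata2 (chromosome 6, 88193891 to 88207032), a transcription factor of stem and mast cells, fell in inv(3) against control by 0.54 on the log2 scale (adjusted p = 0.029), a call that ended without a low-count filter (adjusted p = 0.052) and with a library left out (-0.43, adjusted p = 0.11), and was higher in the double group than in inv(3) by 0.76 ± 0.17 (adjusted p = 0.011). Rpn1 and Sf3b1 passed in no comparison, with adjusted p = 0.065 or above for Rpn1 and 0.16 or above for Sf3b1. Rpn1 did pass in the double group against control by DESeq2 (-0.13, adjusted p = 0.044) and in the averaged effect of inv(3) at a mean CPM of at least 5 (-0.10, adjusted p = 0.031). A point mutation leaves the Sf3b1 level free. EVI1 sequence on the inv(3) allele that the mouse annotation does not list would go uncounted, except for any of its reads placed on Mecom. For these reasons neither Sf3b1 nor Mecom checks the genotype labels.

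Cells with inv(3) alone were compared with control for the effect of the rearrangement. Transcripts of mast cells, basophils and eosinophils fell: 14 of 19 were lower and 1 higher (16 and 1 adjusted over the list alone), with a median log2 change of -1.36. Il1rl1, the IL-33 receptor of mast cells, fell from 18.7 ± 0.874 to 1.31 ± 0.181 CPM (SD, n = 3), a log2 change of -3.83 ± 0.11 (SE). Ear1 and Ear2, ribonucleases of eosinophils, changed by -4.03 ± 0.28 and -2.89 ± 0.21, and Ms4a2, a chain of the IgE receptor, by -2.15 ± 0.13. Prss34, a protease of basophils, changed by -5.11 ± 0.61. The list's adjusted p was 2.8e-13 by camera and 0.0035 with an estimated correlation.

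Stem-cell and early progenitor genes fell as a group in inv(3), with 20 of 28 lower and 2 higher (22 and 2 adjusted over the list alone), a median of -1.78 and adjusted p = 8.8e-11, and adjusted p = 0.46 with an estimated correlation. Flt3, a cytokine receptor of early progenitors, changed by -2.98 ± 0.17, Gng11 by -4.62 ± 0.36 and Mllt3 by -0.95 ± 0.10. Of the Hoxa cluster and its partners, 6 of 11 fell (11 adjusted over the list alone), among them Hoxa9 (-2.75 ± 0.50), Hoxa10 (-3.50 ± 0.57), Pbx3 (-2.15 ± 0.15) and Meis1 (-2.12 ± 0.27). That list had adjusted p = 0.00022 by camera, and adjusted p = 0.48 with an estimated correlation.

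Most erythroid and megakaryocytic genes were lower in inv(3), while some globin genes rose. Of 34 erythroid genes, 24 fell and 5 rose (24 and 5 adjusted over the list alone), with a median of -1.66. Among them were Tal1, a master regulator of the lineage (-1.48 ± 0.12), and Car2 (-2.52 ± 0.25). Gata1, the erythroid and megakaryocytic transcription factor, changed by -1.83 ± 0.24 and its partner Gfi1b by -1.72 ± 0.27. Among those that rose were the globin genes Hbb-b2 and Hbb-bt (4.49 ± 0.43 each), whose equal counts, 288 in control and 6301 in inv(3) summed over 3 libraries, come from near-identical copies. Globin CPM per library, summed over the globin genes, was 14.5 to 20.3 in control and 41.2 to 88.6 in inv(3). Not every globin gene rose: summed over 3 libraries, Hba-a1 had 2461 counts in control and 2002 in inv(3), while Hbb-b1 had 938 and 2253. The erythroid list had adjusted p = 2.8e-05 by camera and adjusted p = 0.48 with an estimated correlation. Of 23 megakaryocyte and platelet genes, 14 fell and 4 rose (15 and 4 adjusted over the list alone), with the integrin Itga2b at -2.32 ± 0.20, Plek at -2.03 ± 0.15 and Treml1 at -3.08 ± 0.32. This list had adjusted p = 4.7e-05 by camera and adjusted p = 0.48 with an estimated correlation. Heme and iron genes fell in 13 of 27 cases and rose in 4 (15 and 5 adjusted over the list alone), including the iron transporter Slc11a2 (-0.59 ± 0.04), with adjusted p = 0.0041, and adjusted p = 0.40 with an estimated correlation.

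Neutrophil genes rose in inv(3). Of 21 genes of mature neutrophils, 13 were higher and 3 lower, the same numbers adjusted over the list alone, with a median of 1.74 and adjusted p = 1.1e-08, and adjusted p = 0.40 with an estimated correlation. Padi4, the enzyme that citrullinates histones in neutrophils, rose from 37.5 ± 4.57 to 220 ± 30.7 CPM (SD, n = 3), a log2 change of 2.55 ± 0.10 (SE). Lrg1 rose by 2.07 ± 0.17 and Olfm4, a granule protein, by 5.39 ± 0.45. Of 20 genes of primary granules and promyelocytes, 12 rose and 2 fell (13 and 2 adjusted over the list alone), such as the serine protease Prss57 (0.64 ± 0.08) and the granule lectin Fcnb (1.20 ± 0.17). That list had adjusted p = 0.0024 by camera and adjusted p = 0.48 with an estimated correlation. Monocyte genes split, with Ms4a4c higher by 3.33 ± 0.12 and Cd68 by 1.57 ± 0.11 while the chemokine receptor Ccr2 changed by -1.56 ± 0.11. Of that list 4 of 23 rose and 12 fell, the same adjusted over the list alone, and its adjusted p = 0.31.

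Interferon-response genes rose in 20 of 37 cases and fell in 2, also when adjusted over the list alone, with a median of 0.36 and adjusted p = 9.3e-06, and adjusted p = 0.48 with an estimated correlation. The antiviral synthetases Oas1a, Oas2 and Oas3 rose by 0.97 ± 0.05, 1.71 ± 0.11 and 1.17 ± 0.13. Macrophage genes fell in 11 of 19 cases and rose in 2 (12 and 2 adjusted over the list alone), with Vcam1 at -2.29 ± 0.22 and Cd163 at -2.93 ± 0.35, and the list had adjusted p = 0.0028 by camera and adjusted p = 0.56 with an estimated correlation. MYC and nucleolar genes fell in 17 of 27 cases (18 adjusted over the list alone) by a median of -0.20, with adjusted p = 0.0035, and adjusted p = 0.48 with an estimated correlation. Oxidative phosphorylation genes fell in 14 of 31 cases (15 adjusted over the list alone) by a median of -0.12, with adjusted p = 0.021, and adjusted p = 0.48 with an estimated correlation. The cholesterol enzyme Sqle changed by -1.01 ± 0.07.

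Several genes were nearly off in one state and on in the other. Summed over the 3 libraries of a group, the neuropeptide gene Npy had 3 counts in control, 1846 in inv(3), 1 in Sf3b1 K700E and 3549 in the double group. Scd3, a fatty-acid desaturase, had 7, 7150, 18 and 11754, and the protocadherin Pcdh11x had 1, 1064, 1 and 1138. In the other direction, Prss34 had 13274 in control, 371 in inv(3), 15456 in Sf3b1 K700E and 157 in the double group, and Tceal8 had 8692, 184, 8378 and 266.

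Across all genes, 2526 rose and 2793 fell in inv(3) against control, 5319 in all at an adjusted p under 0.05 by edgeR. Of these calls, 5107 lay on autosomes. Camera called 16 of 29 lists, of which the mast cell, basophil and eosinophil list and the sex-linked genes held with an estimated correlation.

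**Figure D3:**
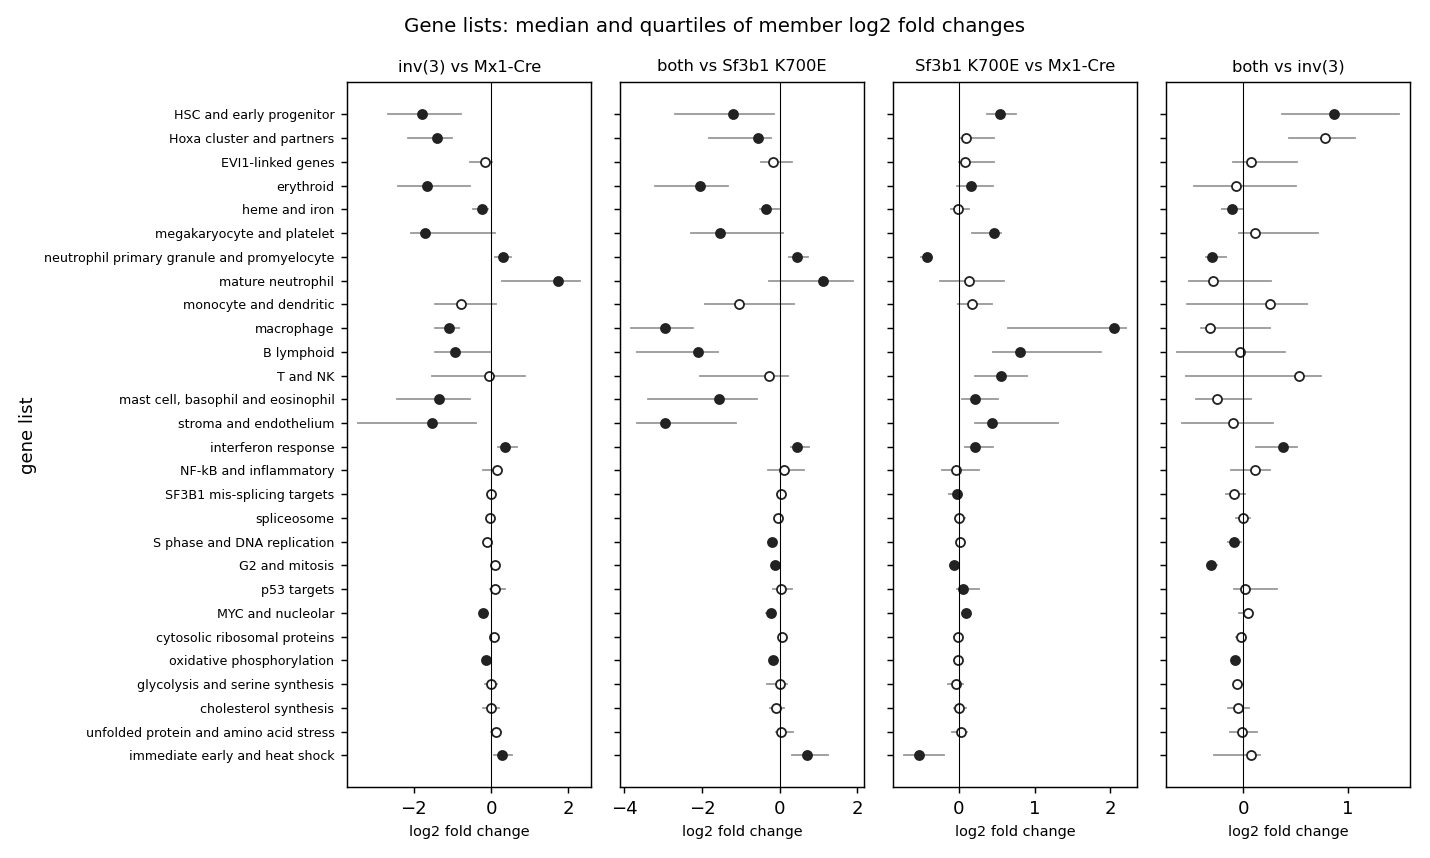
Median (point) and quartiles (line) of the log2 fold changes of each gene list in 4 comparisons, filled where camera with a preset correlation gave an adjusted p under 0.05. The mast cell, basophil and eosinophil list lies at -1.36 in inv(3) against control and the macrophage list at 2.05 in Sf3b1 K700E against control.

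The double group against Sf3b1 K700E asks for the effect of inv(3) where the splicing mutation is present, with Y-linked RNA in all 6 libraries. Il1rl1 changed by -5.41 ± 0.12, Ear2 by -3.80 ± 0.22 and the histamine-forming enzyme Hdc by -2.27 ± 0.11, and 15 of 19 mast cell, basophil and eosinophil genes fell while 1 rose, also when adjusted over the list alone (adjusted p = 1.5e-16, and 0.0051 with an estimated correlation). Padi4 rose by 2.59 ± 0.10, Olfm4 by 5.36 ± 0.44 and Ms4a4c by 4.07 ± 0.12. Flt3 changed by -2.50 ± 0.16, Pbx3 by -2.93 ± 0.15 and Hoxa10 by -4.31 ± 0.57.

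Of the stem-cell list, 19 of 28 fell and 3 rose in the double group against Sf3b1 K700E (19 and 4 adjusted over the list alone), with adjusted p = 3.6e-06, and adjusted p = 0.42 with an estimated correlation. Erythroid genes fell in 28 of 34 cases and rose in 3, also when adjusted over the list alone, with Trim10 at -4.09 ± 0.42 and adjusted p = 4.8e-09, and adjusted p = 0.37 with an estimated correlation. Macrophage genes fell in 17 of 19 cases and rose in 1, also when adjusted over the list alone, by a median of -2.95, with Lpl at -3.05 ± 0.21 and Axl at -2.95 ± 0.31 (adjusted p = 1.3e-11), and adjusted p = 0.36 with an estimated correlation, and Xist changed with them by -2.39 ± 0.35. B-lymphoid genes fell in 17 of 20 cases and rose in 1, also when adjusted over the list alone, such as Cd22 (-4.27 ± 0.36) and Pou2af1 (-3.02 ± 0.34), with adjusted p = 8e-07, and adjusted p = 0.15 with an estimated correlation. Of interferon-response genes, 25 of 37 rose and 3 fell (26 and 3 adjusted over the list alone), with Oas2 higher by 1.70 ± 0.11 (adjusted p = 1.7e-06), and adjusted p = 0.37 with an estimated correlation.

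In total 3537 genes rose and 3227 fell between these groups. The comparisons of inv(3) with control and of the double group with Sf3b1 K700E share no library. They called 4266 genes in common, 2107 higher in both where independent lists would give 649.5, 2136 lower in both where 655.3 would be due, and 23 in opposite directions. Over genes, which are not independent replicates, the 2 sets of log2 changes correlated with r = 0.82 and rho = 0.79. With log2 Xist as a covariate, chosen after the data were seen, the double group differed from Sf3b1 K700E in 1299 genes, and the calls of Axl (-1.44, adjusted p = 0.066), Pou2af1 (-1.64, adjusted p = 0.10) and Hoxa10 (-3.43, adjusted p = 0.056) ended. Xist itself parts these groups, at 4.54 to 5.34 log2 CPM in the double group and 6.27 to 7.71 in Sf3b1 K700E. The fit therefore cannot tell Xist from group well, and the lost calls need not come from Xist-bearing cells.

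Sf3b1 K700E alone was compared with control for the effect of the splicing mutation. Genes of neutrophil primary granules fell: 13 of 20 were lower and none higher (18 lower and 1 higher adjusted over the list alone), by a median of -0.42. Mpo, the myeloperoxidase of those granules, fell from 23100 ± 978 to 15920 ± 1700 CPM (SD, n = 3), a log2 change of -0.54 ± 0.07 (SE). The serine proteases Elane, Prss57 and Ctsg changed by -0.66 ± 0.10, -0.50 ± 0.08 and -0.44 ± 0.09. The list had adjusted p = 1.3e-13 by camera and adjusted p = 0.15 with an estimated correlation. The call of Ctsg ended with a library left out (adjusted p = 0.088).

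Macrophage genes rose in Sf3b1 K700E in 14 of 19 cases with none lower, also when adjusted over the list alone, by a median of 2.05. The mannose receptor Mrc1 rose from 12.3 ± 2.16 to 46.6 ± 16.9 CPM (SD, n = 3), a log2 change of 1.93 ± 0.27 (SE). Axl rose by 2.12 ± 0.30, Spic, a factor of iron-recycling macrophages, by 1.84 ± 0.27 and Adgre1, which encodes the F4/80 antigen, by 0.93 ± 0.12. The list had adjusted p = 1.2e-19 by camera and adjusted p = 0.15 with an estimated correlation. Xist rose beside them by 2.28 ± 0.35.

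B-lymphoid and erythroid lists rose beside the macrophage genes, while of 21 mature neutrophil genes none was called (adjusted p = 0.51) and the monocyte and dendritic list did not pass (3 of 23 higher and 1 lower, adjusted p = 0.18). Of 23 megakaryocyte and platelet genes none was higher and 1 lower, with a median of 0.47 and adjusted p = 0.016, and adjusted p = 0.64 with an estimated correlation. B-lymphoid genes rose in 7 of 20 cases with none lower, also when adjusted over the list alone, among them Pou2af1 (2.84 ± 0.33) and Ebf1 (3.75 ± 0.53). Both had low counts: summed over 3 libraries, Pou2af1 had 24 in control and 181 in Sf3b1 K700E, and Ebf1 had 5 and 76. The list had adjusted p = 9.5e-10 by camera and adjusted p = 0.10 with an estimated correlation. Of 34 erythroid genes, 6 rose and none fell (7 and none adjusted over the list alone), with adjusted p = 5e-07, and adjusted p = 0.48 with an estimated correlation. The hemoglobin genes Hba-a1 (2.69 ± 0.23) and Hbb-b1 (3.82 ± 0.40) were among them, and reads of near-identical globin copies leave the share of each copy uncertain. Alas2, the erythroid enzyme that starts heme synthesis, rose by 3.24 ± 0.45 and the heme oxygenase Hmox1 by 2.11 ± 0.36.

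Genes listed as targets of SF3B1 mis-splicing fell in 5 of 23 cases with none higher (6 adjusted over the list alone). Their splice junctions were not read, so these falls do not show mis-splicing in these cells. Ppox, a heme-synthesis enzyme, changed by -0.35 ± 0.04, Coasy by -0.25 ± 0.05, the phosphatase subunit Ppp2r5a by -0.24 ± 0.05 and the calcium channel Orai2 by -0.20 ± 0.05. This list had adjusted p = 0.022 by camera and adjusted p = 0.16 with an estimated correlation. Left-out libraries ended the calls of Coasy, Ppp2r5a and Orai2 (adjusted p up to 0.095, 0.095 and 0.20). Stem-cell genes rose in 4 of 28 cases (6 adjusted over the list alone), with Slamf1 at 1.24 ± 0.33, Tgm2 at 1.04 ± 0.23 and Esam at 0.94 ± 0.26, a list median of 0.54 and adjusted p = 1.9e-07, and adjusted p = 0.48 with an estimated correlation. All 3 of these genes lost their call with a library left out (adjusted p up to 0.17, 0.084 and 0.20). Interferon-response genes rose in 3 of 37 cases (14 adjusted over the list alone), with Rtp4 at 0.86 ± 0.15, Rsad2 at 0.52 ± 0.11 and Oas2 at 0.44 ± 0.11, and adjusted p = 8.7e-07, and adjusted p = 0.42 with an estimated correlation. The p53 target Zmat3 rose by 0.93 ± 0.13, and the immediate early genes Fos and Fosb changed by -0.99 ± 0.20 and -1.09 ± 0.29. The calls of Rsad2, Oas2, Fos and Fosb also ended with a library left out (adjusted p up to 0.097, 0.13, 0.066 and 0.13), that of Oas2 with limma-voom (0.059) and in the compared groups alone (0.057), and that of Fosb with limma-voom (0.055) and without a low-count filter (0.073).

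In total 542 genes rose and 674 fell, 1216 by edgeR. Camera called 15 of 29 lists and none held with an estimated correlation, where fry called 5 and 15 had an unadjusted camera p under 0.05. The count fell to 168 without Sf3b1 replicate 2 and to 214 without control replicate 2, and was 1866 by DESeq2. With log2 Xist as a covariate it was 0, with 407 genes at an unadjusted p under 0.05.

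**Figure D4:**
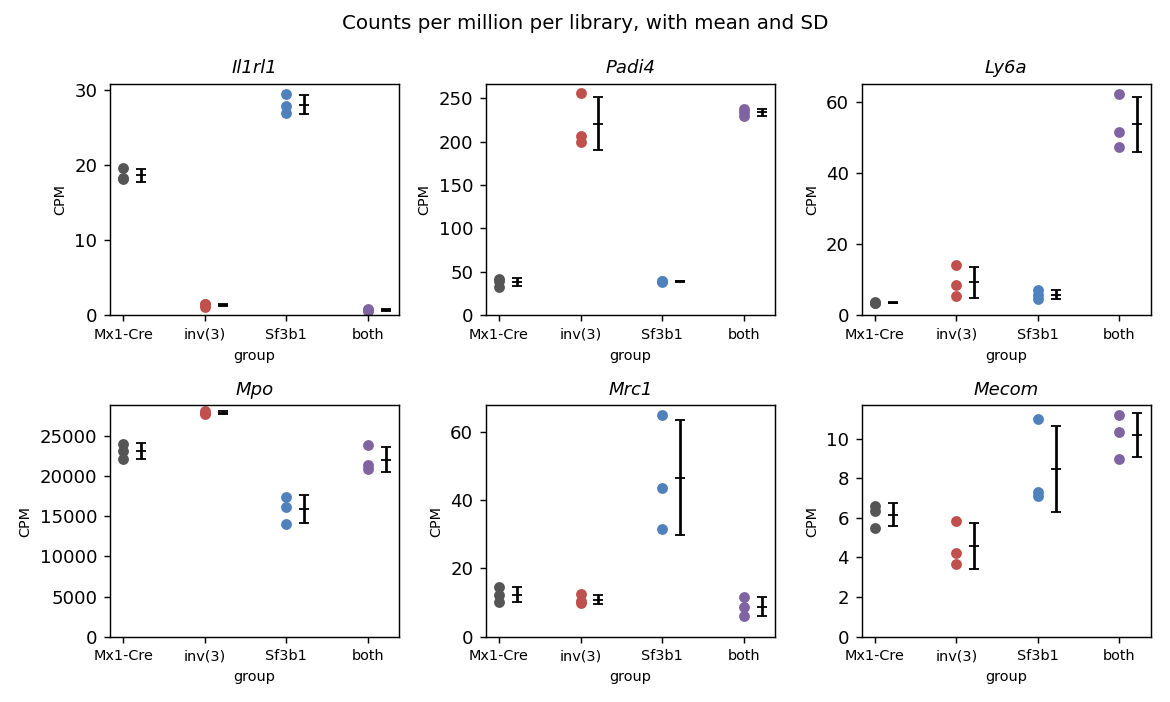
CPM of 6 genes in each library (points), with the group mean and SD (bars), n = 3 per group. Il1rl1 averages 18.7 in control and 1.31 in inv(3), and Ly6a averages 53.8 in the double group and 9.19 in inv(3).

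The double group against inv(3) asks for the effect of Sf3b1 K700E where inv(3) is present. Stem-cell and early progenitor genes rose in 17 of 28 cases with none lower (18 adjusted over the list alone), by a median of 0.87. Ly6a, the Sca-1 antigen of mouse stem cells, rose from 9.19 ± 4.46 to 53.8 ± 7.70 CPM (SD, n = 3), a log2 change of 2.55 ± 0.29 (SE). Esam rose by 1.75 ± 0.29, Pdzk1ip1 by 1.56 ± 0.26 and Myct1 by 1.34 ± 0.16. The list had adjusted p = 9.8e-08 by camera and adjusted p = 0.50 with an estimated correlation. Mecom, Meis1 (1.48 ± 0.26), Angpt1 (1.25 ± 0.15), Adgrg1 (0.88 ± 0.15) and the adhesion molecule Selp (1.39 ± 0.17) rose as well. Not all of these genes rose above control. Summed over 3 libraries, Esam had 778 counts in control, 163 in inv(3) and 564 in the double group, and Meis1 had 8170, 1826 and 5234. By contrast, Ly6a (820, 2124 and 12674), Pdzk1ip1 (1058, 824 and 2496) and Myct1 (3202, 2323 and 6028) lay above control in the double group.

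Genes of G2 and mitosis fell in the double group against inv(3) in 27 of 28 cases (28 adjusted over the list alone), by a median of -0.31. Birc5, which encodes survivin, fell from 93.4 ± 0.775 to 71.6 ± 3.92 CPM (SD, n = 3), a log2 change of -0.38 ± 0.04 (SE). The mitotic regulators Bub1b, Ccnb2 and Tpx2 changed by -0.32 ± 0.04, -0.37 ± 0.05 and -0.31 ± 0.04. The list had adjusted p = 3e-19 by camera and adjusted p = 0.25 with an estimated correlation. Of 30 genes of S phase and replication, 6 fell, also when adjusted over the list alone, such as Rrm2 (-0.36 ± 0.07) and Ccne1 (-0.33 ± 0.06), with adjusted p = 0.012, and adjusted p = 0.66 with an estimated correlation.

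Interferon-response genes rose in 19 of 37 cases (21 adjusted over the list alone), with the GTPase Gbp2 at 1.02 ± 0.10, Rtp4 at 0.95 ± 0.15 and Irgm1 at 0.38 ± 0.06, and adjusted p = 1.2e-06, and adjusted p = 0.47 with an estimated correlation. Primary granule genes fell in 10 of 20 cases (15 lower and 1 higher adjusted over the list alone), including Elane (-0.54 ± 0.10), Mpo (-0.34 ± 0.07) and Cebpe (-0.76 ± 0.19), with adjusted p = 7.4e-05, and adjusted p = 0.47 with an estimated correlation. The antimicrobial peptide gene Camp changed by -1.64 ± 0.34. Of the mast cell, basophil and eosinophil genes, Hdc and Il1rl1 changed by -1.09 ± 0.11 and -0.99 ± 0.13, while the list did not pass (4 of 19 lower and 2 higher, 6 and 3 adjusted over the list alone, adjusted p = 0.075). Mis-splicing targets fell in 7 of 23 cases (9 adjusted over the list alone), with Ppp2r5a at -0.26 ± 0.05, Coasy at -0.19 ± 0.05, Brd9 at -0.17 ± 0.04 and Tmem14c at -0.16 ± 0.04, and the list had adjusted p = 0.075. Macrophage genes had a median of -0.32 with 1 of 19 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.48). The calls of Cebpe, Coasy and Tmem14c ended with a library left out (adjusted p up to 0.057, 0.080 and 0.083), and that of Tmem14c in the compared groups alone (0.052).

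In total 1847 genes rose and 1256 fell, 3103 by edgeR, of which 2968 were autosomal. The count was 1566 without double replicate 3, 1671 without double replicate 1 and 1954 in the compared groups alone. Camera called 8 of 29 lists and only the sex-linked genes held with an estimated correlation. The comparisons of the double group with inv(3) and of Sf3b1 K700E with control share no library, and they called 583 genes in common. Of these 222 were higher in both where independent lists would give 72.8, 343 were lower in both where 61.5 would be due, and 18 went in opposite directions (r = 0.25, rho = 0.47 over genes).

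Averaged over both backgrounds, with 6 libraries against 6, 2162 genes rose and 1850 fell with Sf3b1 K700E. Mecom rose by 0.81 ± 0.14 and Gata2 by 0.65 ± 0.12. Of the stem-cell list 19 of 28 rose (20 adjusted over the list alone), including Ly6a (1.64 ± 0.20), Esam (1.35 ± 0.20) and Myct1 (0.93 ± 0.11), with adjusted p = 1.2e-09, and adjusted p = 0.50 with an estimated correlation. Primary granule genes fell in 17 of 20 cases and rose in 1 (18 and 1 adjusted over the list alone), with adjusted p = 3e-10, and adjusted p = 0.20 with an estimated correlation. Genes of G2 and mitosis fell in 25 of 28 cases (27 adjusted over the list alone), such as Kif23 (-0.25 ± 0.03) and Aurkb (-0.27 ± 0.04), with adjusted p = 4.5e-13, and adjusted p = 0.30 with an estimated correlation. Mis-splicing targets fell in 8 of 23 cases, also when adjusted over the list alone, with adjusted p = 0.025, and adjusted p = 0.20 with an estimated correlation. Interferon-response genes rose in 24 of 37 cases (27 adjusted over the list alone), with adjusted p = 8.5e-09, and adjusted p = 0.42 with an estimated correlation. Camera called 8 of 29 lists, not all of them given here, and 1 held with an estimated correlation.

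The double group against control gives the combined effect of both alleles. Il1rl1 changed by -4.82 ± 0.12, Padi4 rose by 2.64 ± 0.10 and the monocyte gene Ms4a4c by 4.12 ± 0.12. Ly6a rose by 3.96 ± 0.31 and Angpt1 by 1.22 ± 0.15, while Flt3 changed by -2.21 ± 0.16 and Hoxa9 by -2.35 ± 0.48. Interferon-response genes rose in 29 of 37 cases and fell in 1 (30 and 2 adjusted over the list alone), by a median of 0.86, with Oas2 at 2.14 ± 0.11 and adjusted p = 1.6e-14, and adjusted p = 0.24 with an estimated correlation. Genes of G2 and mitosis fell in 21 of 28 cases (25 adjusted over the list alone) by a median of -0.21, with Birc5 at -0.32 ± 0.04 and adjusted p = 1e-04, and adjusted p = 0.55 with an estimated correlation. Mast cell, basophil and eosinophil genes fell in 14 of 19 cases and rose in 1, also when adjusted over the list alone, with adjusted p = 3.2e-16, and 0.0043 with an estimated correlation. In total 2856 genes rose and 2802 fell, and camera called 15 lists.

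The interaction asks whether the change with Sf3b1 K700E differs between libraries with and without inv(3), and it cannot part that from the sex-linked difference of the inv(3) group. In it, 55 genes were higher and 60 lower than the sum of the single effects. Of these 115 genes, 11 lie on the X or Y chromosome, among them Xist and the 4 Y-linked genes, and 2252 of all genes had an unadjusted p under 0.05. Il1rl1 rose in Sf3b1 K700E against control by 0.59 ± 0.09 and fell in the double group against inv(3), an interaction of -1.57 ± 0.16 (adjusted p = 0.00061). Hdc had -0.84 ± 0.15. The macrophage genes Adgre1 and Mrc1 had -1.51 ± 0.17 and -2.24 ± 0.39. Of 19 macrophage genes 3 were lower (15 adjusted over the list alone), with a list median of -2.01. That list had adjusted p = 5.1e-16 by camera and adjusted p = 0.19 with an estimated correlation. Xist had -8.28 ± 0.53, which holds its level of 1952 CPM in inv(3) against 30.4 in the double group. The macrophage mean in inv(3) was 1.99, 0.99 and 1.59 log2 CPM, below the 2.3 to 2.96 of control, so Xist and these genes did not move together there. Genes of G2 and mitosis were lower in 3 of 28 cases (19 adjusted over the list alone), with Cenpf at -0.34 ± 0.06, Bub1b at -0.28 ± 0.05 and adjusted p = 2.5e-13, and adjusted p = 0.24 with an estimated correlation. Gbp2 was higher by 0.72 ± 0.14 and the kinase gene Camk2b by 2.86 ± 0.38. Ly6a, at 1.82 ± 0.41 (adjusted p = 0.067), and Mecom, at 0.69 ± 0.28 (adjusted p = 0.24), did not pass, though Ly6a did by DESeq2 (1.80, adjusted p = 0.0052). The calls of Hdc, Mrc1, Cenpf, Bub1b and Gbp2 ended with a library left out (adjusted p up to 0.10, 0.094, 0.11, 0.11 and 0.13), that of Mrc1 also without a low-count filter and with limma-voom (0.052 in both), and that of Gbp2 at a mean CPM of at least 5 (0.054). The count of genes ranged from 32 to 323 with a library left out and was 622 by DESeq2.

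With inv(3), averaged over both backgrounds, 4084 genes rose and 3843 fell. Of its 17 called lists, the sex-linked genes had the smallest adjusted p (1e-45, and 0.00031 with an estimated correlation), as the inv(3) group lacks Y-linked RNA. In the mast cell, basophil and eosinophil list, 16 of 19 fell and 1 rose (17 and 1 adjusted over the list alone), with adjusted p = 2.4e-16, and 0.0027 with an estimated correlation. Il1rl1 changed by -4.62 ± 0.08, Ms4a4c rose by 3.70 ± 0.09, Padi4 by 2.57 ± 0.07 and Oas1a by 1.02 ± 0.04. Mecom did not differ beyond its error (-0.08 ± 0.14, adjusted p = 0.64).

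The deposited tables give each gene an effective length, a mean over its transcripts weighted by their estimated shares, which moves when isoform use moves. Among 3422 genes with more than 1 listed transcript, 45 changed length with inv(3), 21 longer and 24 shorter (29 without double replicate 3, and 103 with the length column). Mecom, with 2 listed transcripts, lengthened from 3566 ± 42.1 bases (SD, n = 3) in control to 4213 ± 18.9 in inv(3), and from 3708 ± 69.2 in Sf3b1 K700E to 4237 ± 24.4 in the double group, a log2 ratio of 0.216 ± 0.0091 (SE, adjusted p = 2.74e-06). Ece2 (0.490 ± 0.0143) and Mllt3 (0.044 ± 0.0027) lengthened and Ifnar2 (-0.136 ± 0.0101) and Pnkd (-0.241 ± 0.0193) shortened, these 4 being named after their values were seen. With Sf3b1 K700E, 1 gene passed on average over both backgrounds (Psd3, 0.026 ± 0.0027, longer), 1 against control (Tor1aip2, -0.081 ± 0.0086) and 1 in the double group against inv(3) (Ece2, 0.182 ± 0.0202). These genes, too, were named after their values were seen, and 220, 140 and 241 genes had an unadjusted p under 0.05. With a library left out each of these 3 counts ranged from 0 to 3. Mecom did not pass with Sf3b1 K700E, at 0.032 ± 0.0091 on average (adjusted p = 0.397). A mean over annotated transcripts does not see unlisted splice junctions, and reads were not used here. If the inv(3) allele holds EVI1 sequence that the annotation does not list, reads of it placed on Mecom would enter its length, so the change with inv(3) need not be one of isoform use.

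**Figure D5:**
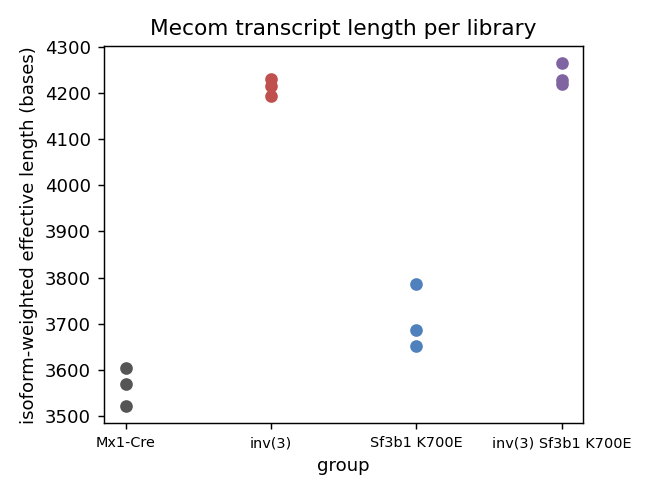
Isoform-weighted effective length of Mecom in bases, 1 point per library, by group. The 6 libraries with inv(3) lie above the 6 without it, with group means of 4213 and 4237 bases against 3566 and 3708.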

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

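The tests that ask for a sex difference, the share of macrophage genes that rose in Sf3b1 K700E, the median of that list in the double group against inv(3), the fits with log2 Xist and the splits of the interaction within inv(3) status were chosen only after the results were seen. The counts over the remaining splits, the Pearson correlation (r) of Xist with macrophage genes within groups and the test for linked genes were set before theirs. For Xist and macrophage genes, the rank correlation (rho) and the value without 2 libraries were not part of that plan.

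The change with Sf3b1 K700E differed between libraries with and without inv(3) in 115 genes and 10 gene lists, by the test of the interaction itself. The test uses the inv(3) group, so it holds the sex-linked difference too: 11 of the 115 genes lie on X or Y and the sex-linked genes are among the 10 lists, of which 1, the sex-linked genes, held with an estimated correlation. Of 100 free splits of the 12 libraries, 3 gave as many genes as the real one and 66 as many lists (up to 20). These splits decide nothing, as they carry the inv(3) effect into the spread or into the contrast, which points to that structure of the samples (the highest other gave 6912 genes and followed inv(3)). With Sf3b1 status split only within the libraries with and without inv(3), 7 of 100 gave as many genes (highest other 1785) and 50 of 100 as many lists (highest other 16). The split with 1785 genes exchanged 2 control with 2 Sf3b1 K700E libraries, so it turns the sign of the Sf3b1 K700E effect there and brings that effect into the contrast. Other splits that turn the sign only with or only without inv(3) can do the same. For this reason these splits do not decide on chance either, and it stays open for both numbers.

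All inv(3) libraries lacked Y-linked RNA, so the differences of that group may come from sex and not from genotype. Of the 5107 autosomal genes called in inv(3) against control, 80.1% (4091, where independent lists would give 1252.9) were called in the same direction in the double group against Sf3b1 K700E, where all 6 libraries held Y-linked RNA. That argues against sex as the cause of the calls as a whole, while the 1016 genes not shared stay open. Of the 2968 autosomal genes called in the double group against inv(3), 18.7% (554, where 130 would be due) were called in the same direction in Sf3b1 K700E against control. The latter comparison called only 1185 autosomal genes, so most of the 2968 could not be shared, and the low share does not speak for sex. Of the 2968, 86.0% had the same sign there, the highest of 20 ways to relabel the control and Sf3b1 K700E libraries. The highest other way (82.9%) exchanged only control replicate 3 and Sf3b1 replicate 1. For the 2414 genes not shared (same sign in 82.7%, highest other 79.0%), 20 ways are too few for a share under 0.05. Sex and an effect of Sf3b1 K700E on the inv(3) background thus cannot be told apart gene by gene, as the design confounds them.

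Macrophage genes stood out in Sf3b1 K700E without inv(3): 73.7% of the 19 measured members rose and none fell, with Mrc1 at 46.6 CPM, a share that restates the pattern and so tells nothing on whether RNA of macrophages passed the lineage-negative gate. Their median was -0.32 in the double group against inv(3), and the list was called in the interaction (adjusted p = 5.1e-16, and adjusted p = 0.19 with an estimated correlation), but both comparisons use the inv(3) group that lacks Y-linked RNA, so an effect of the allele that is alike on both backgrounds stays open. Within groups, over the 9 libraries with Y-linked RNA, log2 Xist and the macrophage mean had r = 0.75 (exact one-sided permutation p = 0.0648) and rho = 0.72 (p = 0.0463) over 216 permutations, with r = 0.73 without the 2 libraries whose deviation of log2 Xist from the group mean lies farthest from the median deviation (Sf3b1 replicate 3 and control replicate 2), so a source in Xist-bearing cells stays open. With log2 Xist as a covariate in these libraries Adgre1 went from 0.93 ± 0.13 to 0.37 ± 0.23 and Mrc1 from 1.93 ± 0.28 to 0.55 ± 0.38 (log2, SE), while Mpo went from -0.54 ± 0.08 to -0.53 ± 0.19 and Ppox from -0.35 ± 0.04 to -0.33 ± 0.10, and other genes moved either way (Ppp2r5a to -0.14, Orai2 to -0.12, Ebf1 to 3.51 and Fosb to -1.33). All gene calls of Sf3b1 K700E against control ended there. The group took 82% of the variance of log2 Xist between Sf3b1 K700E and control, and the errors widened. The folds of Adgre1 and Mrc1 shrank as well, so wider errors alone need not account for every lost call. RNA from recipient cells is a candidate explanation that these fits leave open.

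Large changes marked the libraries with inv(3): 232 autosomal genes changed by at least 3 log2 units the same way in both comparisons for inv(3), 62 higher and 170 lower. Variants linked to the allele or to another passenger locus could give such changes in blocks. The 232 genes made 151 pairs within 5 Mb, leaving out pairs whose symbols share their first 3 letters, where random tested genes made a median of 166 (permutation p = 0.84, 1000 draws), which argues against blocks as the cause of the set as a whole. Such a count cannot show a block of a few genes, and it does not bear on variants spread over the genome. An effect of inv(3) on these genes, or on the mix of progenitors in the gate, was not tested.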

How the results depend on the processing

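The fits on autosomal genes, on the 9 libraries with Y-linked RNA and with log2 Xist as a covariate were chosen only after the results were seen; the other alternatives were planned. Counts under other settings within 1.5 times the reported one are left out, and for each change below the cause was not tested unless given. By DESeq2, Sf3b1 K700E against control had 1866 genes and the interaction 622. In the libraries of the compared groups alone, the double group against inv(3) had 1954 genes. With an estimated correlation, camera called 2 lists in inv(3) against control, 0 in Sf3b1 K700E against control (15 at an unadjusted p under 0.05 with the preset value, 5 by fry), 1 in the double group against each of control, inv(3) and Sf3b1 K700E, 1 in the interaction, 1 for the average of Sf3b1 K700E and 2 for that of inv(3). Fry called 5 lists in Sf3b1 K700E against control, 23 in the double group against control and 15 for the average of Sf3b1 K700E. With the length column, 2 genes changed length for the average of Sf3b1 K700E, 3 against control and 103 for the average of inv(3). With log2 Xist as a covariate, 0 genes passed by edgeR in Sf3b1 K700E against control, where Xist follows the group (407 at an unadjusted p under 0.05, not run with other tools). In the double group against Sf3b1 K700E, where Xist follows the group as well, 1299 passed. In the 9 libraries alone these counts were 1523 and 6938, and on autosomal genes alone the 8 counts ran from 95 for the interaction to 7613 for the average of inv(3).

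Of 18 pairs of libraries with the same replicate number, 3 correlated above 0.1 once groups were removed (-0.379 to 0.27), so the numbers do not pair the samples. Of 12 libraries, 2 correlated best with a library of their own number. With the replicate number as a block, Sf3b1 K700E against control had 654 genes (648 shared with the reported ones), the interaction 60, and the length test of Sf3b1 K700E against control 0 by limma (140 at an unadjusted p under 0.05 without the block). The block also ended the calls of Orai2, Slamf1, Tgm2, Esam, Oas2 and Fosb in Sf3b1 K700E against control (adjusted p = 0.062, 0.056, 0.051, 0.080, 0.062 and 0.078) and of Hdc, Cenpf, Bub1b and Gbp2 in the interaction (0.076, 0.052, 0.087 and 0.080).

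With each library left out in turn, Sf3b1 K700E against control ranged from 168 to 1649 genes. It had 600, 214 and 560 without control replicate 1, 2 and 3, and 168 without Sf3b1 replicate 2. The double group against inv(3) ranged from 1566 to 3342 genes, with 1671 without double replicate 1 and 1566 without double replicate 3, and from 6 to 13 lists, with 13 without double replicate 2. The interaction ranged from 32 to 323 genes: 41, 32 and 40 without control replicate 1, 2 and 3, 217 and 70 without inv(3) replicate 1 and 3, 67 and 51 without Sf3b1 replicate 1 and 2, and 35, 323 and 33 without double replicate 1, 2 and 3. Length calls with Sf3b1 K700E ranged from 0 to 3 on average, from 0 to 3 against control and from 0 to 3 in the double group against inv(3), moving with most libraries. For inv(3) they ranged from 29 to 59, with 29 without double replicate 3. The other gene counts stayed between 4359 and 5564 in inv(3) against control, 4433 and 5964 in the double group against control, 5506 and 7138 in the double group against Sf3b1 K700E, 2908 and 4128 for the average of Sf3b1 K700E, and 7269 and 8178 for that of inv(3).

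Of 180 results for named genes, 50 have an alternative that ends or reverses the call, most of them with log2 Xist as a covariate or with a library left out. Mecom's calls changed with the effective-length offset, which by its construction divides by a length that rises with inv(3). Signs turned mainly in genes that did not pass. The Sf3b1 gene in Sf3b1 K700E against control moved from -0.02 to 0.01 at a mean CPM of at least 5, 0.1 with Xist and 0.02 with a library left out. Averaged over Sf3b1 status, inv(3) moved Sf3b1 from 0.00 to -0.03 at that filter, to 0 with RLE, DESeq2, the offset or autosomes alone and to -0.01 with a library left out, Mecom from -0.08 to 0.03 with a library left out, and the interaction moved Rpn1 from -0.03 to 0.01. With Xist as a covariate, the double group against Sf3b1 K700E moved Rpn1 from -0.09 to 0.02, Sf3b1 from 0.07 to -0.06 and Xist to 0 by construction, and Oas2 in Sf3b1 K700E against control went from 0.44 to -0.05. Depth limits what can be said of the genes the low-count filter removed, as 13755 of 24411 were tested.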

Other observations

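The counts over other splits of the libraries were planned, and no test in this part was chosen after its result was seen.

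Other lists were read in inv(3) as well. Of 25 p53 targets, 5 rose and 2 fell in inv(3) against control, also when adjusted over the list alone, with Trp53inp1 at 0.70 ± 0.09 and the BH3-only gene Pmaip1 at 1.52 ± 0.22 (list adjusted p = 0.21). Thy1 and Gzmb, lymphoid surface and granule genes, rose by 3.14 ± 0.26 and 1.69 ± 0.19, while Cd27 changed by -2.69 ± 0.46 and the T and NK list did not pass (adjusted p = 0.73). Col1a1 rose by 3.07 ± 0.35, from 16 counts in control to 133 in inv(3) summed over 3 libraries. The collagen gene Col1a2 had 163 and 12 counts and Pdgfrb 4126 and 289, so stromal genes did not rise together. The endothelial genes Kdr and Emcn changed by -3.20 ± 0.35 and -3.95 ± 0.49. Of 11 stroma and endothelium genes 6 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.012 by camera, and adjusted p = 0.48 with an estimated correlation). Cytosolic ribosomal protein genes had 3 of 85 higher and 4 lower (0 and 2 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.12). B-lymphoid genes fell in 8 of 20 cases and rose in 2, also when adjusted over the list alone (adjusted p = 0.023, and adjusted p = 0.48 with an estimated correlation), and immediate early and heat shock genes rose in 8 of 21 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.047, and adjusted p = 0.68 with an estimated correlation).

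In the double group against inv(3), the glucose transporter Slc2a3 rose by 0.55 ± 0.09 while the glycolytic enzymes Pgam1, Hk2 and Gpi1 changed by -0.37 ± 0.06, -0.40 ± 0.07 and -0.28 ± 0.06, and the list did not pass (adjusted p = 0.20). Sesn1 and Trp53inp1, targets of p53, rose by 0.66 ± 0.10 and 0.58 ± 0.09. The stress gene Ddit4 rose by 0.57 ± 0.10, Il6 by 1.26 ± 0.29, and Tnf changed by -0.70 ± 0.17, a call that ended in the compared groups alone (adjusted p = 0.062) and with a library left out (0.053). Summed over 3 libraries, the protease gene Capn11 had 633 counts in control, 2 in inv(3), 270 in Sf3b1 K700E and 2154 in the double group.

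Other splits of the libraries were counted for each comparison. Where 3 libraries are set against 3 there are 10 splits, too few for a share under 0.05. As many genes as the real split came from 1 of 10 splits, the real one, in inv(3) against control (5319, highest other 0), the double group against control (5658, highest other 0), the double group against inv(3) (3103, highest other 0) and the double group against Sf3b1 K700E (6764, highest other 0). In Sf3b1 K700E against control it was also 1 of 10, with 1216 genes and 997 in the highest other split, which joined control replicate 1 with Sf3b1 replicates 2 and 3. Once groups were removed, control replicate 1 correlated with Sf3b1 replicate 3 at 0.401 and control replicate 3 with Sf3b1 replicate 1 at 0.318, the highest values between groups, so these libraries share a structure across the compared groups. For lists it was 2 of 10 in inv(3) against control (16, highest other 16), 1 of 10 in Sf3b1 K700E against control (15, highest other 13), 2 of 10 in the double group against control (15, highest other 16), 7 of 10 against inv(3) (8, highest other 15) and 4 of 10 against Sf3b1 K700E (17, highest other 18). For length it was 2 of 10 in Sf3b1 K700E against control (1, highest other 8) and 3 of 10 in the double group against inv(3) (1, highest other 1).

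For the averaged effects 100 splits were counted. For genes, 1 of 100 splits gave as many with Sf3b1 K700E (4012, highest other 1785) and 1 of 100 with inv(3) (7927, highest other 2313). A chance split of these libraries is thus unlikely to give either count. The other splits carry the group difference into the spread, which lowers their counts. They do not part genotype from the sex-linked difference of the inv(3) group, or from a shared origin of replicates. For lists, 65 of 100 gave as many with Sf3b1 K700E (8, highest other 17) and 22 of 100 with inv(3) (17, highest other 20), so chance is not excluded for these numbers of lists. For length, 7 of 100 gave as many with Sf3b1 K700E (1, highest other 95), so chance is not excluded and the highest split points to a structure of the samples. With inv(3), 1 of 100 gave as many (45, highest other 2), so a chance split is unlikely to give that count, within the same limits as for genes.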
